A study of Mus musculus with 9 samples.

How the data were processed

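Gene expression was measured by droplet single-cell RNA sequencing in 9 mouse libraries. Per the labels, 2 libraries held macrophages sorted from the pancreas of untreated Flt3-Cre;LSL-YFP mice of 8 weeks, 1 of YFP-negative and 1 of YFP-positive cells. The other 7 held immune cells sorted from pancreatic tumours of mice of 12 weeks. Of these, 4 came from tumours grown in the pancreas from injected KP2 cells, a line made from a genetically engineered tumour mouse (KPC), and carry the names p21WT (2 libraries) and p21CE (2 libraries). The labels do not explain the name CE, and they give the same strain, Lysm-Cre;LSL-Cdkn1a-YFP, for all 4. The last 3 came from KPC mice, 1 without a named treatment, 1 given vehicle and 1 given chemotherapy, which per the labels' protocols was gemcitabine at 50 mg/kg and paclitaxel at 5 mg/kg every 5 days. Per the labels' protocols the sort gates differed between steady-state pancreas, the p21 and untreated KPC tumours, and the vehicle and chemotherapy tumours, and tissue was digested for 15 min (steady state) or 25 min (tumour).

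The deposited files hold UMI counts per gene and cell barcode, integers that the authors had not normalised. Per the submitters' processing notes they came from Cell Ranger 4.0.0 with the mm10 build, while per the file headers the version was 3.1.0 for the 2 steady-state libraries and the untreated KPC library and 4.0.0 for the rest. Reads were not used here. The gene annotation release is not given in the sources used here, and the number of genes differed between sets of libraries, so genes were matched by Ensembl identifier. Gene positions are from GENCODE M21 on mm10 and are 1-based. The p21 libraries also carried a YFP entry.

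Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored with the Scrublet method in scanpy 1.11.5. Its automatic threshold called almost no cell in 7 libraries, so the highest-scoring cells were removed up to an expected rate of 0.8% per 1000 cells. In the p21WT libraries the threshold called 1701 and 1908 cells, of which 953 and 969 were removed. In the p21CE libraries it called 2 and 0, and 424 and 329 were removed. Called cells thus remained in the p21WT libraries, a difference that follows the tested groups. Clusters were made separately for the steady-state, p21, KPC, and vehicle with chemotherapy libraries from 2000 variable genes, 30 principal components and 20 neighbours. Leiden clustering (igraph 0.11.9) used a resolution of 0.3 for steady state and 0.1 elsewhere, a second round at 0.1 within clusters of at least 300 cells, and seed 1. Cdkn1a and the proliferation list were kept out of the variable genes. Clusters were first named after 20 fixed marker lists as macrophage-like and so on, and clusters with no clear marker set stayed unnamed. For any cluster in a separate list, matched by its leading gene, the class was then set by hand in place of the marker rule.

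Counts were summed per library and cell class, since cells of 1 library are not replicates. Total UMIs per library ranged from 76756908 to 161941553. Only p21CE against p21WT had 2 libraries per group, and it was tested in macrophage-like, monocyte-like, cDC1-like and cDC2-like cells with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 (TMM factors, filterByExpr, Benjamini-Hochberg adjusted p under 0.05, two-sided). The cDC classes are conventional dendritic cells (DC) of type 1 and type 2. The 15 gene lists covered proliferation, p53 targets and CDK inhibitors, NF-kB inflammatory cytokines, interferon response, MHC class I and class II presentation, tissue-resident and monocyte-derived macrophage genes, alternative activation, lipid and lysosome genes, hypoxia and glycolysis, matrix remodelling, phagocytic receptors, complement, and immediate-early and heat-shock genes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The marker lists of other cell types were tested alike, as a family of their own. CPM (counts per 1000000) are relative to the class total, scaled by TMM factors in the tested comparison.

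Comparisons of 1 library with 1 library have no test. They give CPM with exact Poisson intervals, ratios with exact conditional binomial intervals, shares of cells with exact binomial (Clopper-Pearson) intervals, and list medians with their percentile among 10000 random lists matched on expression in 20 bins. Genes with under 10 UMIs were left out there. Intervals are 95% and cover counting error only. For steady state against untreated tumour, genes were counted for which both steady-state libraries lay outside the range of the 4 untreated tumour libraries. Shares of cycling cells were taken after thinning every cell to 5000 UMIs, because depth per cell differed, and again at 2000 UMIs for shallower classes. Class shares are given as values without a test, as planned before the counts were opened. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, and no test built on a model of the counts was made.

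The gene lists, the marker lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Cdkn1a comes first everywhere. In p21CE against p21WT the rule names the 10 genes with the largest log2 fold change in each direction in macrophage-like cells (5 in other classes) among genes past the threshold, with mean CPM of at least 20 and libraries of the 2 groups apart. In the other comparisons it names 10 each among genes with CPM of at least 50 and, for 1 library against 1, a ratio interval wholly beyond 2-fold. Up to 4 members of each list come in addition, or 2 where none passed. Markers of other cell types, mitochondrial, ribosomal, antigen receptor, predicted and sex-linked genes are left out of the rankings.

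The alternatives were RLE factors, DESeq2 1.42.0, no low-count filter, a replicate number as a block, each library left out, doublets kept, cells with at least 1000 genes and at most 5% mitochondrial UMIs, cells with at least 200 genes for shares, macrophage-like with monocyte-like cells, cells without Mki67 or Top2a UMIs, and cells without T or B cell markers. The pipeline was tested on simulated data made from these counts. With 200 changed genes in macrophage-like cells, edgeR recovered 77.6% at 1.5-fold and 83.6% at 2-fold and called 0.191% of unchanged genes. The same shares in monocyte-like cells were 41.8%, 67.2% and 0.200%. In the data 6851 of 13851 genes were called in macrophage-like cells, far more than the 200 changed here, so these shares may not carry over. In the simulated pairs of single libraries, 95.7% and 95.9% of ratio intervals held the true ratio. That coverage holds for the simulated counts only. Real counts spread more widely than counting error. Chi-square per degree of freedom was 2.06 to 2.37 between random parts of the same p21 library. It was 3.61 between parts of the p21WT libraries and 6.56 between parts of the p21CE libraries. The ratio intervals for single libraries may thus be too narrow. Other tools were Python 3.11.15, anndata 0.12.19, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.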

Results

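Single-cell RNA counts were collected from macrophages of the normal mouse pancreas and from immune cells of pancreatic ductal adenocarcinoma (PDAC). The 2 steady-state libraries held YFP-negative and YFP-positive macrophages of Flt3-Cre;LSL-YFP mice, in which cells with a Flt3-expressing ancestor, such as those derived from bone marrow progenitors, carry YFP. They held 76756908 and 79218789 UMIs. The p21WT libraries held 159100693 and 149563517 UMIs, and the p21CE libraries 113031499 and 103446294. The KPC, KPC vehicle and KPC chemotherapy libraries, 1 each, held 161941553, 130296694 and 119735005. After filtering, 7073 and 5291 steady-state cells, 9263 and 9362 p21WT cells, 6550 and 5730 p21CE cells, and 8010, 10659 and 7337 KPC, vehicle and chemotherapy cells remained. Macrophage-like cells numbered 6545 and 4748 in steady state, 3868 and 3877 in p21WT, 2020 and 1742 in p21CE, and 4172, 5112 and 3538 in the KPC set. The labels do not say that replicate libraries came from separate animals, so p-values measure the spread between libraries, which may be technical.

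The comparison of p21CE with p21WT tumours asked how macrophages of KP2 tumours differ when a Cre-activated Cdkn1a-YFP construct is present in myeloid cells. Cdkn1a encodes p21, an inhibitor of cyclin-dependent kinases that stops cells before S phase. The gene (ENSMUSG00000023067) lies on chromosome 17 at 29090976 to 29100727 on mm10. The YFP entry told the groups apart as labelled. A YFP UMI was found in 79.4% (77.5 to 81.1) and 81.8% (79.9 to 83.6) of p21CE macrophage-like cells, against 0.0259% of 3868 and 0.0258% of 3877 p21WT cells, which is 1 cell each. In B cell-like p21CE cells, the background, it was found in 3.22% and 3.43%, at median UMIs of 4592 and 5166 against 20810 and 22574 in macrophage-like cells. Cdkn1a itself had 905 ± 4.97 CPM in p21WT and 777 ± 21.7 CPM in p21CE macrophage-like cells (SD, n = 2). It fell by 0.22 on the log2 scale (SE 0.05, edgeR adjusted p = 0.0053), a call that did not hold with either p21WT library left out. Whether transcripts of the construct are counted under Cdkn1a is not given in the sources used here, so this value does not measure p21 from the construct. Cdkn1a also fell in cDC2-like cells, from 618 ± 12.5 to 534 ± 2.45 CPM (edgeR adjusted p = 0.0242), with the same limit. It did not pass the threshold in monocyte-like cells, with 626 ± 43.4 and 655 ± 18.9 CPM (edgeR adjusted p = 0.724), or in cDC1-like cells, with 178 ± 1.87 and 134 ± 41.1 CPM (edgeR adjusted p = 0.125).

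Macrophage-like cells of p21CE tumours had less of the mRNAs of the cell cycle. Of the 40 proliferation genes 38 fell and 0 rose, with a median log2 fold change of -1.82. Birc5, which guards chromosome segregation, fell 5.41-fold, from 57.2 ± 2.65 to 10.6 ± 2.39 CPM (edgeR adjusted p = 6.62e-08). Pclaf, a partner of the replication clamp PCNA, fell 6.61-fold from 70.9 ± 4.12 to 10.7 ± 5.18 CPM (edgeR adjusted p = 1.59e-06). The kinetochore genes Cenpf (5.56-fold) and Cenpe (5.20-fold), the ubiquitin ligase partner Ube2c (4.98-fold), the thymidine kinase Tk1 (5.15-fold) and the cyclin Ccnb2 (4.35-fold) fell with them. Hist1h1b (7.56-fold), Hist1h2ae (4.63-fold), Cdca3 (4.76-fold) and Stmn1 (4.72-fold) fell as well. The list had an adjusted p of 6.79e-75 in camera, and adjusted p = 0.127 with an estimated correlation. The class joined a macrophage cluster with a proliferating one, in which 35.6% of cells were called doublets and removed and no macrophage marker was among the 10 leading genes. The fall thus does not separate fewer proliferating cells from less mRNA within cells. In cells without an Mki67 or Top2a UMI the list median was -0.44, but such cells may still be cycling. Detection depends on depth, since in the first p21WT library 33.3% of cells had such a UMI without thinning and 16.9% at 5000 UMIs. The share of cells with an Mki67 or Top2a UMI at equal depth was 16.9% (15.7 to 18.2) and 17.96% (16.7 to 19.2) in p21WT, and 8.44% (7.22 to 9.79) and 9.93% (8.52 to 11.5) in p21CE. The means were 17.4 ± 0.731% and 9.18 ± 1.05%, a difference of -8.26 points. Counting cells with at least 2 UMIs over the whole list instead did not tell libraries apart, since 99.2% and 98.8% of cells met it.

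At 2000 UMIs per cell, the macrophage-like share was 10.5% and 11.1% in p21WT and 4.35% and 4.96% in p21CE. B cell-like cells had 5.24% and 3.97% in p21WT and 4.49% and 3.13% in p21CE. Median UMIs of B cell-like cells were 4056 and 3768.5 in p21WT and 4592 and 5166 in p21CE, against 17538, 16321, 20810 and 22574 in macrophage-like cells. The p21CE macrophage share thus lay at the level of B cell-like cells. In neutrophil-like cells the share was 8.21% and 9.68% in p21WT and 4.196% and 5.61% in p21CE. A lower share was thus not particular to macrophage-like cells. In neutrophil-like cells the macrophage markers Apoe (1539 and 579 CPM) and C1qb (282 and 97.6 CPM) were also lower in p21CE. Whether the mix of cells in that class changed was not tested. A YFP UMI was found in 74.4% and 82.5% of neutrophil-like p21CE cells.

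**Figure D1:**
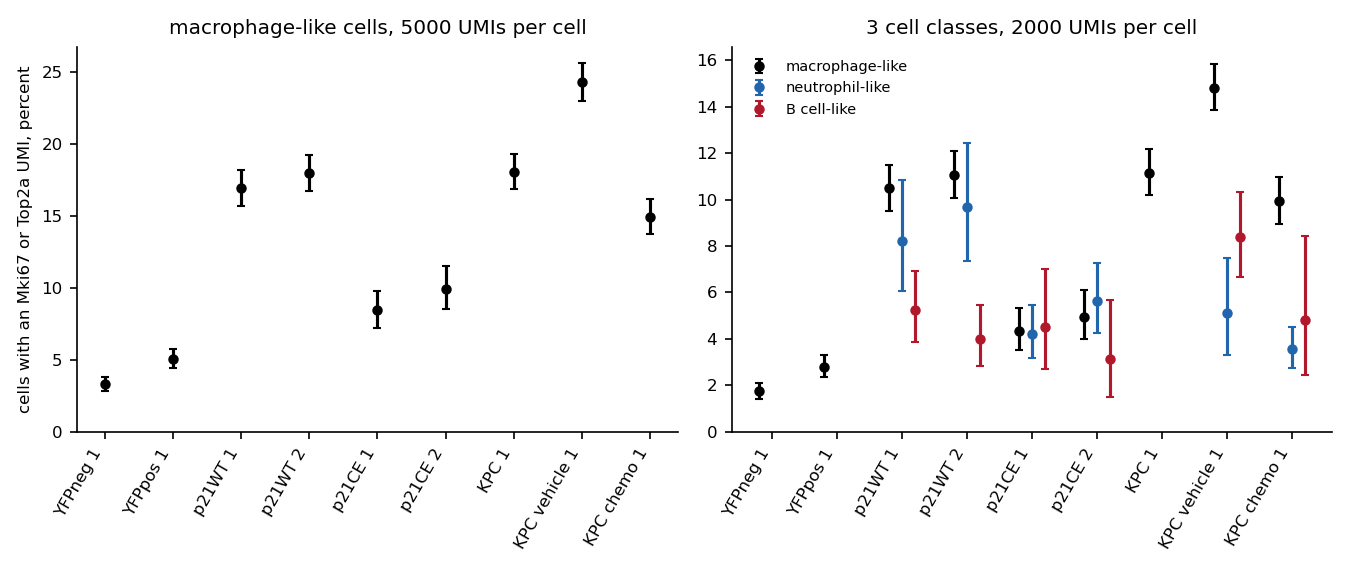
Share of cells with an Mki67 or Top2a UMI (percent, vertical axis) in each library, in macrophage-like cells thinned to 5000 UMIs (left) and in 3 cell classes thinned to 2000 UMIs (right). Points are libraries and bars are 95% exact binomial intervals, and in macrophage-like cells both p21CE libraries lie below both p21WT libraries.

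Outside the cell cycle, Retnla, a secreted product of IL-4-activated macrophages, fell from 813 ± 15.1 to 66.6 ± 8.19 CPM (12.2-fold, edgeR adjusted p = 1.19e-09). Lif, an IL-6 family cytokine, rose 4.68-fold from 12.0 ± 0.415 to 56.1 ± 3.72 CPM (edgeR adjusted p = 5.29e-09), and Il6 rose 3.49-fold from 75.8 ± 1.32 to 264 ± 41.5 CPM. The neutrophil attractants Cxcl3 (4.27-fold, 386 ± 23.4 CPM in p21CE) and Ppbp (4.51-fold, 24.2 ± 1.41 CPM) rose, as did the plasminogen activator inhibitor Serpine1 (4.29-fold, 189 ± 13.5 CPM). Vcan (3.09-fold), a matrix proteoglycan, Ccl24 (3.06-fold), an eosinophil attractant, Acod1 (3.103-fold), which makes itaconate, and Upp1 (3.22-fold), which breaks down uridine, rose as well. Cxcl3, Acod1 and Upp1 were higher in neutrophil-like cells, with 860, 539.8 and 339 CPM in p21CE, than in macrophage-like cells. In all, 6851 of 13851 tested genes differed in macrophage-like cells, 3594 up and 3257 down. Most shifts were small, with a median size of 0.35 among the genes that differed, and 273 genes rose and 548 fell by at least 2-fold.

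Inflammatory and oxygen-stress programmes rose. Of 30 NF-kB cytokine genes 24 rose and 2 fell (median 0.35, camera adjusted p = 3.97e-16, adjusted p = 0.127 with an estimated correlation). Ccl2, which recruits monocytes, rose from 483 ± 23.8 to 1248 ± 70.4 CPM (edgeR adjusted p = 1.35e-07), and Il23a from 20.7 to 44.7 CPM, beside 130.2 and 216 CPM in neutrophil-like cells. Of 26 hypoxia and glycolysis genes 24 rose over all genes and 25 adjusted over the list alone, and none fell (median 0.54, camera adjusted p = 1.01e-22, adjusted p = 0.121 with an estimated correlation). Its members Ero1l, an oxidase of protein folding (77.8 to 168 CPM), Slc2a1, a glucose importer (75.7 to 132 CPM), Slc16a3, a lactate exporter (122 to 205 CPM), and Pfkl, an enzyme of glycolysis (62.5 to 107 CPM), all rose. Of these, Ero1l, Slc2a1 and Slc16a3 were higher in neutrophil-like p21CE cells (201, 203 and 478 CPM). Ero1l, Slc2a1, Slc16a3 and Pfkl were also higher in p21CE than in p21WT in every class examined. B cell-like cells had 16.9 and 25.98 CPM of Ero1l and 31.96 and 43.6 CPM of Slc2a1 in p21WT and p21CE. They had 9.22 and 17.8 CPM of Slc16a3 and 24.5 and 29.7 CPM of Pfkl. The rise of these named genes is thus not particular to macrophage-like cells. Matrix remodelling had 13 of 26 genes up and 5 down (median 0.45, camera adjusted p = 1.78e-07, adjusted p = 0.121 with an estimated correlation), with the proteases Adam8 (97.9 to 225 CPM, beside 229.7 CPM in neutrophil-like p21CE cells) and Mmp19 (88.2 to 197 CPM). Alternative activation had 15 of 22 genes up and 4 down (median 0.23, camera adjusted p = 0.00568, adjusted p = 0.146 with an estimated correlation). Arg1, which depletes arginine, rose from 1045 ± 35.4 to 2107 ± 52.6 CPM and Hmox1, which degrades heme, from 162 to 283 CPM, while Retnla fell.

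Receptors and stress genes moved in the same direction. Of 22 phagocytic receptors 12 rose and 4 fell (median 0.14, camera adjusted p = 0.00427, adjusted p = 0.146 with an estimated correlation), among them the integrin Itgam (238 to 483 CPM, beside 671 CPM in neutrophil-like p21CE cells) and the scavenger receptors Msr1 (158 to 255 CPM), Lrp1 (166 to 235 CPM) and Stab1 (120 to 168 CPM). Of 26 immediate-early and heat-shock genes 14 rose and 4 fell (median 0.15, camera adjusted p = 0.00264, adjusted p = 0.207 with an estimated correlation). The chaperones Hspa1a (129 to 259 CPM), Hspa1b (71.0 to 165 CPM) and Hsph1 (37.2 to 66.7 CPM), and Ier3 (858 to 1247 CPM), were the leading ones. The chaperones were higher in p21CE in each of the 7 classes examined, with Hspa1a at 28.7 and 69.9 CPM, Hspa1b at 26.3 and 79.9 CPM and Hsph1 at 44.1 and 91.7 CPM in B cell-like cells, so their rise is not particular to macrophage-like cells. Ier3 was higher in neutrophil-like p21CE cells (1513 CPM). The phagocytic list, like that of alternative activation, did not pass with the second p21WT library left out. Monocyte-derived genes had 11 of 20 up and 5 down (median 0.39, camera adjusted p = 1.57e-06, adjusted p = 0.121 with an estimated correlation), including the homing receptor Sell (22.6 to 45.3 CPM), the matrix protein Emilin2 (154 to 293 CPM) and the lectin Chil3 (188 to 350 CPM). Neutrophil-like p21CE cells had more of all 3 (164, 401 and 2939 CPM), so neutrophil RNA in the macrophage-like class may carry part of these rises.

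Antigen presentation fell. Of 14 MHC class II genes 12 fell and 1 rose (median -0.52, camera adjusted p = 5.35e-09, adjusted p = 0.121 with an estimated correlation). H2-Ab1 fell from 5980 ± 171 to 3239 ± 22.4 CPM (edgeR adjusted p = 2.31e-06), H2-Eb1 from 5118 ± 139 to 2779 ± 28.7 CPM, and their transactivator Ciita from 80.3 to 46.4 CPM, while the T cell co-stimulator Cd80 rose from 73.7 to 130.3 CPM, beside 244 CPM in neutrophil-like p21CE cells. Of 18 MHC class I genes 12 fell and 2 rose (median -0.26, camera adjusted p = 0.00395, adjusted p = 0.225 with an estimated correlation). The immunoproteasome subunits Psmb8 (381 to 275 CPM) and Psmb9 (142 to 95.1 CPM) and H2-Q4 (39.4 to 25.8 CPM) fell, and the peptide trimmer Erap1 rose (31.0 to 42.0 CPM). Psmb8 and Psmb9 were lower in p21CE in every class examined, with 392 and 314 CPM and 174 and 141 CPM in B cell-like cells. Their fall is thus not particular to macrophage-like cells, whereas H2-Q4 was not lower in B cell-like cells (89.7 and 105 CPM). Interferon response genes had 12 of 34 down and 1 up (median -0.12, camera adjusted p = 0.0353, adjusted p = 0.418 with an estimated correlation), among them the antiviral genes Bst2 (306 to 221 CPM), Xaf1 (32.2 to 23.6 CPM), Rtp4 (37.3 to 28.5 CPM) and Gbp3 (40.9 to 30.3 CPM). That list did not pass in fry, with the second library of either group left out, with doublets kept, with stricter cell filters or with monocyte-like cells added. Bst2 was also lower in p21CE in every class examined, with 74.2 and 61.2 CPM in B cell-like cells. Complement components had 7 of 12 down and 3 up (median -0.30, camera adjusted p = 0.00264, adjusted p = 0.146 with an estimated correlation). C4b (87.0 to 30.3 CPM), C1qb (3855 to 2339 CPM) and C1qc (2212 to 1462 CPM) fell, and the C5a receptor C5ar1 rose (209 to 297 CPM, beside 411 CPM in neutrophil-like p21CE cells).

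Lipid and lysosome genes split, with 14 of 26 down and 7 up (median -0.17, camera adjusted p = 0.0157, adjusted p = 0.54 with an estimated correlation). The phospholipid carrier Pltp (194 to 107 CPM), the phosphatase Acp5 (369 to 232 CPM) and Cd63 (729 to 417 CPM) fell, while the matricellular Spp1 rose from 1073 ± 51.2 to 2919 ± 354 CPM. That list did not pass in fry or with the second p21CE library left out. Tissue-resident genes split as well, with 14 of 26 down and 9 up (median -0.33), and did not pass as a list unless the first p21WT library, cycling cells or cells with T or B cell markers were left out (camera adjusted p = 0.121, and adjusted p = 0.54 with an estimated correlation). Igf1 (33.4 to 16.6 CPM), the lectin Cd209f (3.35 to 0.457 CPM) and the folate receptor Folr2 (71.1 to 42.0 CPM) were among those that fell. The list of p53 targets and CDK inhibitors also did not pass (camera adjusted p = 0.388, adjusted p = 0.54 with an estimated correlation). Of its 23 genes 5 rose and 10 fell, and its median of 0.04 and mean of -0.20 differ in sign, with the camera direction following the mean. Mdm2, the p53 ligase, rose from 55.9 to 74.7 CPM, and Cdkn2c (9.74 to 3.27 CPM), Cdkn2a (2.90 to 1.19 CPM) and Phlda3 (3.97 to 1.81 CPM) fell. For all lists but hypoxia and glycolysis, the counts adjusted over the list alone equalled those over all genes. Of the 15 lists, 13 passed in camera with the preset correlation, 0 in camera with an estimated correlation (5 at unadjusted p under 0.05) and 11 in fry.

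**Figure D2:**
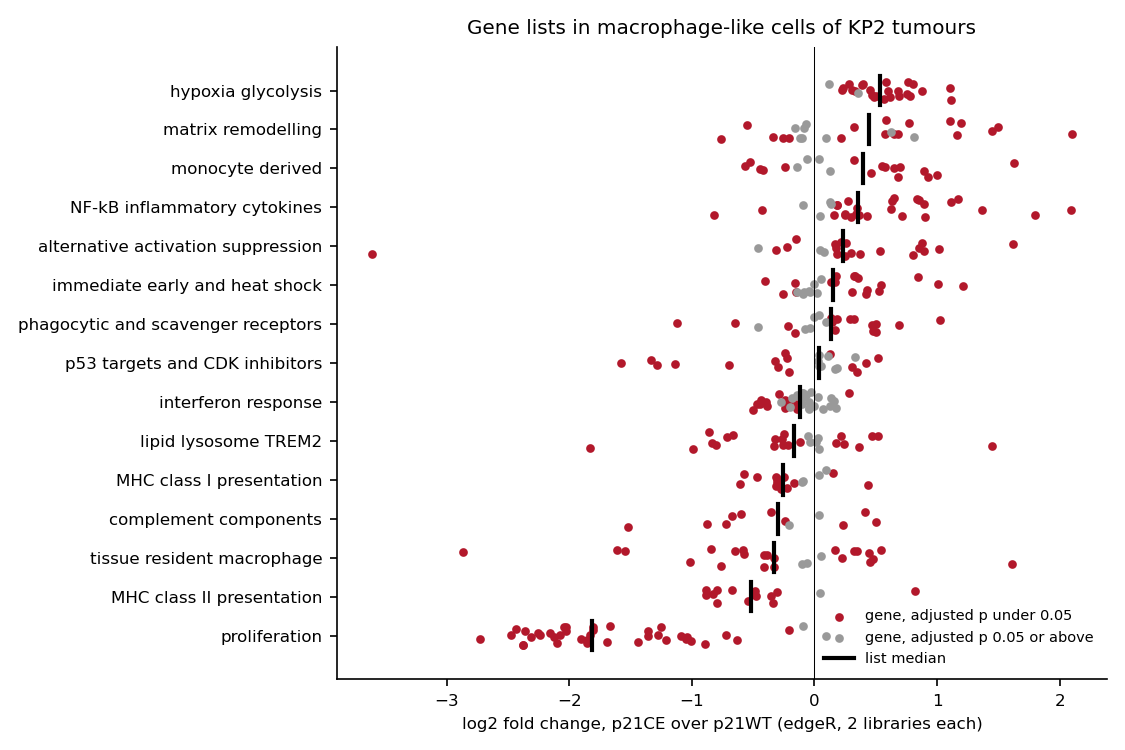
Log2 fold change of p21CE over p21WT in macrophage-like cells (horizontal axis, edgeR, 2 libraries each) for the genes of 15 lists. Points are genes, coloured where the adjusted p was under 0.05, and lines are list medians, lowest for proliferation (-1.82) and highest for hypoxia and glycolysis (0.54).

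Markers of other cell types moved within the macrophage-like class too. All 13 neutrophil markers rose (median 1.10, camera adjusted p = 2.66e-20, adjusted p = 0.25 with an estimated correlation), as did 10 of 13 monocyte markers (median 0.55, camera adjusted p = 1.04e-13, adjusted p = 0.25 with an estimated correlation). Plasma cell markers had 7 of 10 up (camera adjusted p = 0.00682), and 11 of 11 B cell (camera adjusted p = 1.02e-07), 8 of 15 T cell (camera adjusted p = 0.000801) and 12 of 26 acinar markers fell (camera adjusted p = 0.000275), each with adjusted p = 0.677 with an estimated correlation. Macrophage markers had 8 of 12 down and 2 up (median -0.28, camera adjusted p = 0.00016, adjusted p = 0.677 with an estimated correlation). The lists of cDC1, cDC2, migratory DC, pDC, NK cell, innate lymphoid, mast cell, eosinophil, fibroblast, endothelial, epithelial and erythroid markers did not pass, with camera adjusted p from 0.108 to 0.838.

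In monocyte-like cells, where the Lysm promoter is also active, proliferation genes fell and NF-kB cytokines rose. Their YFP-positive share was 84.1% and 93.2% in p21CE, and 806 of 8711 genes differed, 392 up and 414 down (335 in DESeq2). Csf1, the growth factor of macrophages, rose from 5.15 ± 2.41 to 39.7 ± 4.84 CPM (log2 2.97, edgeR adjusted p = 1.3e-06). Neutrophil-like cells, which were more frequent in p21CE, had 216 and 363 CPM of Csf1, and B cell-like cells, the background, 5.95 and 7.48 CPM. Lif (5.09 to 29.2 CPM) and the alarmin Il1a (17.1 to 66.1 CPM) rose as well, beside 1.59 and 5.93 CPM (Lif) and 21.3 and 29.9 CPM (Il1a) in B cell-like cells, and 267 and 460.5 CPM of Il1a in neutrophil-like cells. Serpine1 passed the threshold (7.15 to 27.4 CPM) but was at the level of B cell-like cells (6.32 and 25.7 CPM), so its value may be free macrophage RNA. Ube2c (106 ± 27.8 to 21.9 ± 22.7 CPM), Cenpf (27.4 to 5.92 CPM), Top2a (48.9 to 13.1 CPM), Nusap1 (21.9 to 6.09 CPM) and Cdk1 (20.2 to 6.10 CPM), all mitotic genes, fell, though Cdk1 did not with the second p21CE library left out. Of 35 proliferation genes 19 fell, 25 adjusted over the list alone (median -1.11, camera adjusted p = 2.02e-21, adjusted p = 0.202 with an estimated correlation). Of 29 NF-kB genes 19 rose, 20 adjusted over the list alone (median 0.59, camera adjusted p = 4.61e-30, adjusted p = 0.131 with an estimated correlation). Of 20 monocyte-derived genes 6 fell and 2 rose, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.349 with an estimated correlation).

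In conventional DC the fall of cell cycle genes was small or absent. A YFP UMI was found in 14.1% and 21.5% of cDC1-like and in 20.3% and 27.1% of cDC2-like p21CE cells. Median UMIs were 24730 and 27805.5 in cDC1-like and 19801 and 20831 in cDC2-like cells, against 4592 and 5166 in B cell-like cells. The shares alone thus do not place these classes above the background. Relative to the class total, YFP had 31.1 CPM in cDC1-like and 58.7 CPM in cDC2-like p21CE cells. It had 6.504 CPM in B cell-like and 6.998 CPM in T and innate lymphoid-like p21CE cells. These values argue against background alone as the source of YFP in both DC classes. In cDC2-like cells 1890 of 10936 genes differed, 951 up and 939 down (882 in DESeq2), but of 40 proliferation genes 3 rose and 3 fell (1 and 3 adjusted over the list alone; median 0.01, camera adjusted p = 0.945, adjusted p = 0.974 with an estimated correlation). Hypoxia and glycolysis genes rose in 20 of 26, 24 adjusted over the list alone (median 0.41, camera adjusted p = 3.21e-22, adjusted p = 0.185 with an estimated correlation), and NF-kB genes in 19 of 30, 21 alone (median 0.30, camera adjusted p = 1.31e-14, adjusted p = 0.185 with an estimated correlation). Setd5, a chromatin regulator, rose from 35.5 ± 1.07 to 142 ± 0.585 CPM (edgeR adjusted p = 1.6e-09), and so did Serpine1 (20.7 to 74.1 CPM, beside 6.32 and 25.7 CPM in B cell-like cells). Cxcl3 (7.60 to 20.5 CPM) and the monocyte attractant Ccl7 (15.5 to 37.5 CPM) passed the threshold but did not stand clear of B cell-like cells (7.14 and 43.9 CPM of Cxcl3, 21.6 and 34.7 CPM of Ccl7). The lectins Cd209d (119 to 31.0 CPM) and Cd209e (22.3 to 6.34 CPM) fell. The T cell attractant Ccl5 (46.9 ± 27.9 to 14.9 CPM), Ly6a (50.0 to 16.8 CPM) and the lysozyme Lyz1 (25.2 to 10.4 CPM) also passed the threshold. B cell-like cells had 32.9 and 13.1 CPM of Ccl5, 644 and 413 CPM of Ly6a and 29.2 and 15.4 CPM of Lyz1, so these 3 values may be free RNA of other cells.

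In cDC1-like cells, the cross-presenting DC, 379 of 10140 genes differed, 151 up and 228 down. With a p21WT library left out the count was 28 or 40, and it was 1051 with no low-count filter, so it depends on the libraries and settings. Of the genes named here, all but Setd5 and Retnla lost their call with a p21WT library left out. Setd5 rose from 39.2 to 125 CPM (edgeR adjusted p = 6.74e-06), and the adhesion gene Cdh17 (7.74 to 20.8 CPM) and the GTPase Gbp2 (9.31 to 21.9 CPM) rose, beside 12.2 and 16.3 CPM (Cdh17) and 21.8 and 29.6 CPM (Gbp2) in B cell-like cells. Tmem176a (49.6 to 24.0 CPM), the antiviral Oasl1 (20.1 to 9.85 CPM) and Cxcl10 (47.7 to 23.7 CPM) fell. Tmem176a had 28.6 and 15.8 CPM in B cell-like and 596 and 254 CPM in macrophage-like cells, so free macrophage RNA may carry part of its fall. Ccl7 (10.1 to 24.7 CPM), Retnla (20.3 ± 13.8 to 1.28 ± 0.659 CPM) and the lipid carrier Apoe (496 to 248 CPM) also passed the threshold. In B cell-like cells these 3 macrophage genes had no less (21.6 and 34.7 CPM of Ccl7, 22.1 and 2.89 CPM of Retnla, 884 and 944 CPM of Apoe), so their values here may be free macrophage RNA. Of 40 proliferation genes 4 fell, 8 adjusted over the list alone (median -0.21, camera adjusted p = 0.000112, adjusted p = 0.72 with an estimated correlation).

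The p21CE tumours held fewer macrophage-like and more neutrophil-like cells among the cells that passed the gate. Macrophage-like cells made up 41.6 ± 0.244% of p21WT and 30.6 ± 0.310% of p21CE cells (SD, n = 2), and neutrophil-like cells 6.69 ± 0.155% and 19.4 ± 2.11%. T and innate lymphoid-like cells had 14.1 ± 0.296% and 9.64 ± 0.622%, and B cell-like cells 9.92 ± 0.389% and 5.89 ± 0.400%. Monocyte-like cells had 2.05 ± 0.198% and 3.16 ± 0.252%, cDC1-like 2.30 ± 0.0705% and 2.90 ± 0.199%, cDC2-like 5.64 ± 0.172% and 6.69 ± 0.554%, NK-like 3.54 ± 0.156% and 2.95 ± 0.124%, and plasmacytoid DC-like cells 1.93 ± 0.0387% and 0.867 ± 0.264%. In each of these classes both libraries of one group lay beyond both of the other, whereas migratory DC-like cells (3.47% and 3.32%) overlapped. The gate removed cells with neutrophil, eosinophil, T cell and B cell surface markers, so these shares are of cells that escaped it. Shares are given as values without a test. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, and no test built on a model of the counts was made.

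**Figure D3:**
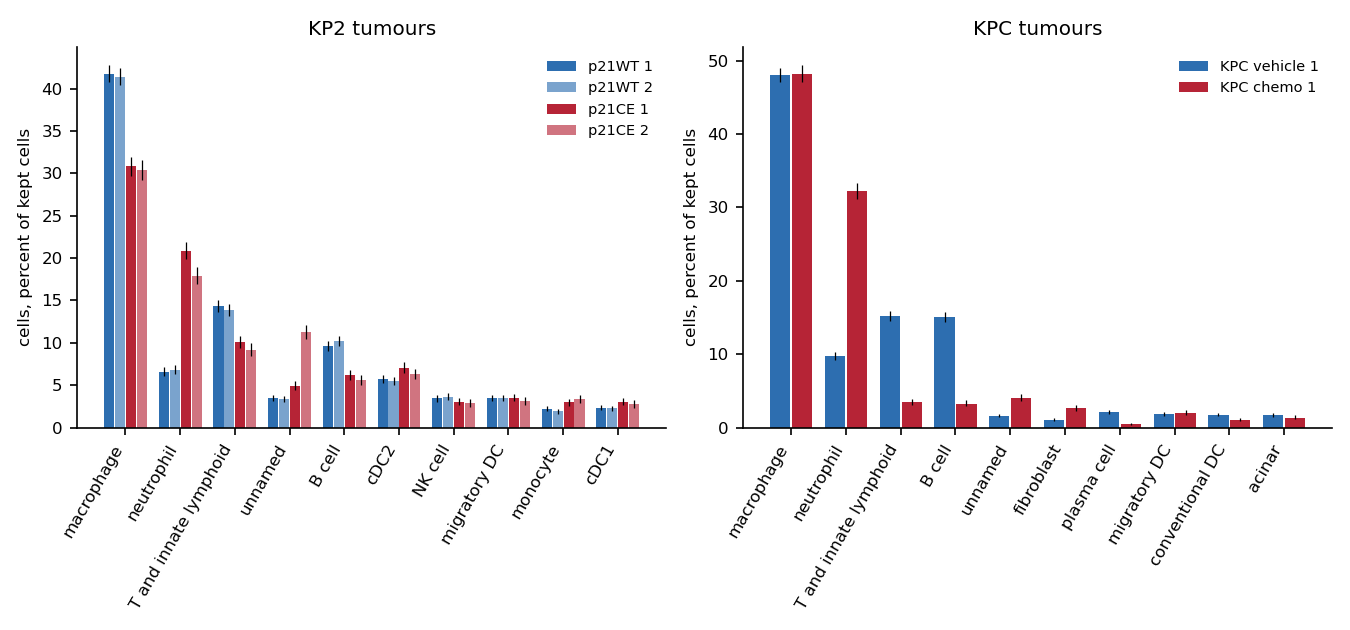
Share of kept cells in each class (percent, vertical axis) for the p21WT and p21CE libraries (left) and the KPC vehicle and chemotherapy libraries (right). Bars are libraries with 95% exact binomial intervals, and neutrophil-like cells are higher in p21CE and after chemotherapy.

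The comparison of YFP-negative with YFP-positive macrophages of the normal pancreas asked how macrophages of different ancestry differ at steady state. It has 1 library per group and no replicate check, so it compares libraries. Cdkn1a had 96.5 CPM (94.1 to 99.04) in YFP-negative and 145 CPM (142 to 148) in YFP-positive cells, a ratio of 0.665 (0.643 to 0.687). In YFP-negative cells only 3 genes met the naming rule as higher, Colec12, a scavenger receptor (121 against 52.9 CPM, 2.29-fold), Pla2g2d, a lipase linked to resolution of inflammation (156 against 73.2 CPM, 2.13-fold), and Cyr61, a matrix signal (115 against 54.3 CPM, 2.11-fold). Higher in YFP-positive cells were Lyz1 (852 against 94.3 CPM, 9.03-fold), Napsa (57.8 against 7.35 CPM, 7.87-fold) and fibronectin, Fn1 (889.7 against 119 CPM, 7.49-fold). The chemokine receptor Ccr2, which brings monocytes into tissue, had 600.0 against 128 CPM (4.70-fold). Cytip (6.11-fold), Olfm1 (4.72-fold), Id2 (4.26-fold), Saa3 (4.08-fold), Alcam (3.92-fold) and Emb (3.59-fold) were the others.

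The macrophage-like class was a different mixture of clusters in the 2 libraries. A cluster led by Retnla, Lyz1 and Lpl held 8.16% of YFP-negative and 39.4% of YFP-positive macrophage-like cells, and the other main clusters held 48.0% and 41.8% against 36.7% and 22.5%. The values here are of the whole class and do not separate this mixture from differences within a cluster. Of 20 monocyte-derived genes 19 were lower in YFP-negative cells (median -1.63, percentile 0 of random lists), with S100a4 at 182 against 650.3 CPM and S100a6 at 319 against 1025 CPM. Of 26 tissue-resident genes 25 were higher (median 0.51, percentile 100), among them Selenop, a selenium carrier (4032 against 2985 CPM), and the platelet-type chemokine Pf4 (3721 against 2118 CPM). Complement genes were higher in 9 of 12 (median 0.36, percentile 100), with C1qa at 5961 against 4564 CPM and C1qb at 5297 against 4214 CPM. Proliferation genes were lower in 39 of 40 (median -0.35, percentile 0), with H2afz at 484 against 599 CPM and Tuba1b at 379.6 against 414 CPM. The share of cells with an Mki67 or Top2a UMI was 3.31% (2.85 to 3.82) in YFP-negative and 5.05% (4.41 to 5.75) in YFP-positive cells, 1.74 points higher in the latter (0.922 to 2.58), or 4.23 points without thinning. In YFP-negative cells lower medians also came from matrix remodelling (-0.88, 17 of 25 lower, percentile 0), hypoxia and glycolysis (-0.46, 22 of 26 lower, percentile 0; Gapdh 477 against 671 CPM), MHC class II (-0.38, 12 of 14 lower, percentile 0; H2-Aa 5669 against 7308 CPM) and NF-kB cytokines (-0.29, 21 of 30 lower, percentile 0; Il1b 53.7 against 123 CPM).

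Alternative activation genes had a median of -0.20 (percentile 0.11), p53 targets -0.10 (percentile 3.22; Bax 132 against 143 CPM), MHC class I -0.10 (percentile 3.69; B2m 1796 against 1885 CPM) and lipid and lysosome genes -0.08 (percentile 6.35, and -0.04 with stricter cell filters). In the last list Spp1 (30.7 against 81.9 CPM), the lipase Lpl (197 against 509.9 CPM), Fabp5 (68.7 against 175 CPM) and Lgals3 (272 against 557 CPM) were lower in YFP-negative cells. Phagocytic receptors had 0.08 (percentile 95.5, and 0.18 with stricter cell filters; the scavenger receptor Marco 37.1 against 132 CPM), interferon response genes 0.09 (percentile 98.6; Bst2 374 against 284 CPM), and immediate-early and heat-shock genes 0.01 (percentile 60.3, and 0.02 with stricter cell filters; Fos 1987 against 1968 CPM). Markers of other types differed, with 13 of 13 monocyte markers lower in YFP-negative cells (median -2.23) and lower cDC2 (-1.90), T cell (-1.71), neutrophil (-1.37) and cDC1 (-1.36) medians. The medians of acinar (0.69, 29 of 29 higher), endocrine (0.79), fibroblast (0.71) and erythroid (4.51) markers were higher.

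The comparison of chemotherapy with vehicle in KPC tumours asked which immune cells and macrophage genes differ after gemcitabine and paclitaxel, a chain terminator and a microtubule drug. It again has 1 library per group and no replicate check. Neutrophil-like cells made up 9.77% of vehicle and 32.2% of chemotherapy cells, a difference of 22.5 points (21.3 to 23.7). B cell-like cells went from 15.0% to 3.27% (-11.7 points, -12.5 to -10.9; -7.12 with stricter cell filters) and T and innate lymphoid-like cells from 15.2% to 3.46% (-11.7 points, -12.5 to -10.9). Macrophage-like cells had 48.0% and 48.2% (0.262 points, -1.23 to 1.76), but with stricter cell filters the difference was -8.94 points. Fibroblast-like cells had 1.02% and 2.63%, plasma cell-like 2.07% and 0.491%, NK-like 0.657% and 0.0818%, and conventional DC-like cells 1.77% and 1.06%. The share of macrophage-like cells with an Mki67 or Top2a UMI was 24.3% (23.02 to 25.6) with vehicle and 14.9% (13.7 to 16.2) with chemotherapy (-9.36 points, -11.1 to -7.57). At 2000 UMIs it was 14.8% and 9.94%, beside 8.37% and 4.80% in B cell-like cells, whose median UMIs were 2366.5 and 3066.5 against 10639 and 17233 in macrophage-like cells.

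In macrophage-like cells Cdkn1a had 960.3 CPM (953 to 968) with vehicle and 756 CPM (749.7 to 763) with chemotherapy, a ratio of 0.788. The monocyte attractants Ccl8 and Ccl7 were higher after chemotherapy. Ccl8 had 88.5 against 9.71 CPM (9.11-fold), and Ccl7 386 against 54.2 CPM (7.12-fold). Also higher were the collagenase Mmp13 (4.91-fold), Ccl12 (130.0 against 26.8 CPM, 4.85-fold), the co-stimulatory receptor Tnfrsf9 (3.93-fold), Cxcl3 (3.79-fold) and Ccl2 (545 against 144 CPM, 3.78-fold). Pf4 (3.70-fold), Folr2 (3.38-fold) and the membrane protein Ms4a7 (3.20-fold) were also higher. Lower after chemotherapy were the S-phase histone Hist1h2ap (3.19 against 56.4 CPM, 17.7-fold), the chaperones Hspa1b (33.5 against 226 CPM, 6.74-fold) and Hspa1a (4.67-fold), and Tnf (41.5 against 188 CPM, 4.52-fold). Il23a (4.11-fold), Mucl1 (3.39-fold), Ccdc80 (2.76-fold), the phosphatase Dusp2 (2.75-fold), Tnfsf9 (2.74-fold) and the adhesion receptor Icam1 (2.59-fold) were lower as well.

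Of the lists, tissue-resident genes stood highest after chemotherapy, with 25 of 26 genes higher (median 1.05, percentile 100). The transcription factor Maf had 107 against 37.0 CPM and the scavenger receptor Stab1 96.5 against 38.5 CPM. Interferon response genes were higher in 24 of 33 (median 0.66, percentile 100), with Bst2 at 194 against 123 CPM, although Cxcl10 was lower (105 against 182 CPM; log2 -0.80, and -0.53 with stricter cell filters). Hypoxia and glycolysis genes were higher in 25 of 26 (median 0.61, percentile 100), with the mitophagy gene Bnip3 at 72.1 against 22.8 CPM, and the angiogenic factor Vegfa had 219.7 against 74.4 CPM. Matrix remodelling (0.41, 18 of 26 higher), complement (0.39, 8 of 12 higher; C1qa 3297 against 2454 CPM), MHC class I (0.24, 15 of 18 higher; B2m 1853 against 1128 CPM), phagocytic receptors (0.24, 16 of 23 higher), alternative activation (0.20, 17 of 22 higher; Retnla 575 against 241 CPM) and lipid genes (0.19, 20 of 26 higher, 0.11 with stricter cell filters; Spp1 2475 against 1208 CPM) followed. Proliferation genes had a median of 0.12 (24 of 40 higher), although the share of cells with an Mki67 or Top2a UMI was lower. Immediate-early and heat-shock genes had -0.13 (17 of 26 lower, percentile 0.48; Jun 280.4 against 606 CPM, Dnajb1 39.8 against 84.3 CPM). MHC class II (0.03), p53 targets (0.02), NF-kB cytokines (-0.01) and monocyte-derived genes (-0.02) lay within the middle of random lists, and the sign of all but the p53 list turned with TMM factors or stricter cell filters, with Fn1 at 3726 against 4666 CPM in the last. Of other types' markers, neutrophil (1.04, 11 of 12 higher), fibroblast (1.17) and erythroid (5.52) medians were higher, and B cell (-0.83), T cell (-0.65) and epithelial (-0.58) medians lower.

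The comparison of untreated tumours with steady state asked how tumour macrophages differ from those of the healthy pancreas. Cdkn1a had 121 ± 34.4 CPM in the 2 steady-state and 882 ± 70.1 CPM in the 4 untreated tumour libraries (SD), 7.30-fold higher in tumours. The share of cells with an Mki67 or Top2a UMI was 4.18 ± 1.23% and 19.3 ± 3.37%, 15.1 points higher in tumours (27.8 without thinning), and in no tumour library was it below 16.9%. Il1b, the inflammasome cytokine, had 88.3 ± 48.9 and 3729 ± 769 CPM (42.2-fold), and the elastase Mmp12 11.7 ± 11.8 and 1019.9 ± 190.0 CPM (86.9-fold). Gates, ages, digestion times and the software version in the file headers differed between these libraries, and so did sex, since Xist had under 0.1 CPM in both steady-state and 747 to 813 CPM in the p21WT and vehicle libraries. The differences cannot be put down to the tumour alone. Of 3354 genes with at least 50 CPM, the steady-state libraries lay above all tumour libraries in 1204 (35.9%) and below all in 1119 (33.4%), where chance gives 6.67% each. With TMM factors the counts were 845 above and 1484 below of 3267.

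Some of the genes highest in tumours over steady state differed widely between the tumour libraries. Plet1, with 1 UMI in steady state, had 259 ± 181 CPM in tumours and Car4, with 2 UMIs, 61.7 ± 93.3 CPM. Car4 had 202 CPM in the KPC vehicle library but 12.4 to 19.2 CPM in the other 3, and 166 CPM in neutrophil-like against 13.04 CPM in macrophage-like cells of p21WT, so neutrophil RNA may carry it. Inhba, an activin subunit, had 0.122 and 55.4 ± 14.0 CPM (453-fold), Tnfrsf9 0.0646 and 82.3 ± 42.8 CPM, Nrg1, a growth factor for epithelium, 0.0648 and 112 ± 93.4 CPM, and Nt5e, which makes adenosine, 0.0483 and 60.8 ± 15.9 CPM. Il1a had 1.04 and 205 ± 70.9 CPM (196-fold). Wfdc21 had 133 ± 156 CPM in tumours (552-fold), with 348 CPM in the vehicle and 16.2 and 20.4 CPM in the p21WT libraries. AU020206 had 86.5 ± 63.4 CPM (194-fold) but 2.26 CPM in the untreated KPC library. Chil3 had 5.01 and 1265 ± 2095 CPM (252-fold), with 4406 CPM in the vehicle library and 185 to 283 CPM in the others. Neutrophil-like p21WT cells had 3707 CPM of Chil3 and 267 CPM of Il1a, against 185 and 161 CPM in macrophage-like cells. Neutrophil RNA may thus carry part of these 2 ratios as well. Highest in steady state were the lectins Cd209g (184 ± 65.3 and 0.652 ± 0.505 CPM, 282-fold) and Cd209f (489 ± 186 and 1.91 ± 1.64 CPM, 257-fold). The hemoglobin scavenger Cd163 (54.8-fold), the apoptotic cell receptor Timd4 (53.5-fold) and the hyaluronan receptor Lyve1 (49.9-fold), all marks of resident macrophages, were also higher in steady state, with Cyr61 (86.3-fold), Chp2 (58.7-fold), Fxyd2 (43.2-fold), Plekhg5 (36.1-fold) and Rasgrp3 (35.7-fold).

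Of 40 proliferation genes, 36 had both steady-state libraries below all tumour libraries and none above (median 1.64, percentile 100), as for Mki67 (15.4 ± 2.95 and 78.0 ± 14.8 CPM), Top2a (18.6 ± 5.13 and 78.1 ± 9.07 CPM), Pclaf (6.17-fold) and Ube2c (3.97-fold). All 26 tissue-resident genes had steady state above (median -3.33, percentile 0). A p21 cluster led by Saa3, Prg4 and Marco, with 234 and 207 p21WT cells and C1qa in 99.5% of its cells, stayed unnamed and was not in the tumour class. With it added all 26 were still above (median -3.18), with smaller ratios for Timd4 and Lyve1. Hypoxia and glycolysis genes were below in 25 of 26 (median 1.70, percentile 100; Pgk1 31.5-fold, Slc2a1 16.1-fold), NF-kB cytokines in 23 of 30 (median 2.55, percentile 100; Osm 40.6-fold, Cxcl3 29.8-fold) and matrix genes in 17 of 26 (median 2.70, percentile 100; Timp1 27.9-fold). Cxcl3 had 491 CPM in neutrophil-like against 88.8 CPM in macrophage-like p21WT cells, and Slc2a1 109 against 74.5 CPM, so neutrophil RNA may carry part of their ratios. Monocyte-derived genes were below in 12 of 20 (median 1.51; Vcan 84.6-fold, Thbs1 44.2-fold), alternative activation in 12 of 22 (median 0.71; Arg1 28.3 ± 28.6 and 1231 ± 291 CPM, Vegfa 120.3-fold, while Clec10a was 9.66-fold higher in steady state), and immediate-early genes in 14 of 26 (median 0.54; Nr4a1 5.02-fold, while Egr1 was 3.79-fold higher in steady state). Of 25 p53 targets 12 were below and 6 above (median 0.43; Pmaip1 2.39-fold and Plk2 2.21-fold higher in tumours, Sesn1 10.5-fold higher in steady state).

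Complement genes had steady state above in 9 of 12 and below in 3 (median -0.84; Cfh 4.3997-fold and C4b 2.67-fold higher in steady state, C3 3.39-fold higher in tumours). The medians of the other 5 lists lay within the middle 95% of random lists. Interferon response genes had 14 of 32 above and 1 below (median -0.37, percentile 6.94; Rtp4 2.56-fold higher in steady state, Cxcl10 5.19-fold higher in tumours). Their median was -0.13 (percentile 70.5) over the p21WT and -0.73 (percentile 0.02) over the KPC libraries alone, and -1.38 in the vehicle library. MHC class I genes had 8 of 18 above and 1 below (median -0.29, percentile 5.42; H2-T23 2.10-fold higher in steady state), with -0.08 (percentile 31.0) over the p21WT and -0.46 (percentile 0.93) over the KPC libraries alone. With TMM factors the counts above and below were 9 and 2 for interferon response, 3 and 1 for MHC class I and 1 and 6 for MHC class II genes. MHC class II had 2 of 14 above and 4 below (median 0.30, percentile 94.6, 0.42 over the p21WT and -0.01 over the KPC libraries alone; Ctss 2.86-fold and Cd80 10.1-fold higher in tumours, H2-Aa 1.32-fold higher in steady state), lipid and lysosome genes 8 of 26 above and 11 below (median 0.27, percentile 88.6; Acp5 58.0-fold and Spp1 20.4-fold higher in tumours, Cd36 22.4-fold higher in steady state), and phagocytic receptors 7 of 23 above and 10 below (median 0.21, percentile 81.8, 0.08 over the p21WT and 0.36, percentile 98.1, over the KPC libraries alone; Itgax 15.1-fold higher in tumours, Colec12 14.8-fold higher in steady state). Of other types' markers, T cell (6.14), NK cell (5.14), neutrophil (4.83) and B cell (4.62) medians were higher in tumours, and acinar (-4.92), endocrine (-3.05) and macrophage (-0.72) medians higher in steady state.

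**Figure D4:**
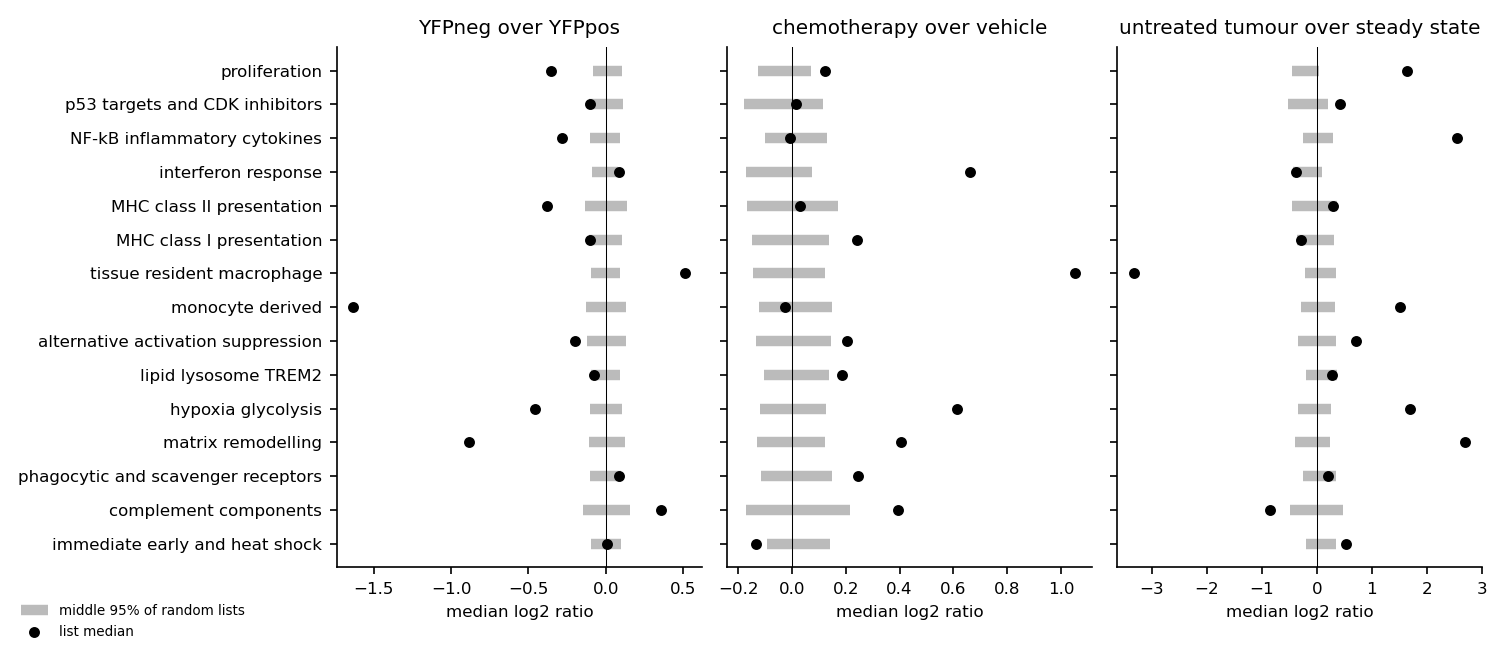
Median log2 ratio of 15 gene lists (horizontal axis) for YFP-negative over YFP-positive, chemotherapy over vehicle, and untreated tumour over steady state in macrophage-like cells. Points are list medians and grey bars hold the middle 95% of random lists, and tissue-resident genes lie at 0.51, 1.05 and -3.33.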

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

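Of the tests in this part, that of Setd5 in cDC2-like cells without a YFP UMI was chosen before its result was seen, and the other tests, among them that of Setd5 in T and innate lymphoid-like cells, were chosen only after the result was seen.

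The p21CE effect differed between macrophage-like and cDC2-like cells of the same libraries, and this difference drew attention to 8 lists. The effect on the proliferation list was lower in macrophage-like cells by a median log2 of -1.86 (camera adjusted p = 3.39e-63, adjusted p = 0.165 with an estimated correlation). MHC class II genes differed by -0.52 (camera adjusted p = 2.24e-19, adjusted p = 0.147 with an estimated correlation) and monocyte-derived genes by 0.48 (camera adjusted p = 3.95e-13, adjusted p = 0.147 with an estimated correlation). Complement genes differed by -0.32 (camera adjusted p = 0.00392, adjusted p = 0.238 with an estimated correlation), lipid and lysosome genes by -0.17 (camera adjusted p = 4.25e-06, adjusted p = 0.289 with an estimated correlation) and MHC class I genes by -0.11 (camera adjusted p = 6.06e-05, adjusted p = 0.165 with an estimated correlation). NF-kB cytokines differed by only 0.051 (camera adjusted p = 0.0256, adjusted p = 0.268 with an estimated correlation) and hypoxia and glycolysis genes by 0.082 (camera adjusted p = 0.0123, adjusted p = 0.519 with an estimated correlation). In edgeR 1683 of 13221 genes differed in their p21CE effect between the classes. Against cDC1-like cells the proliferation list differed by -1.78 (camera adjusted p = 8.55e-34, adjusted p = 0.405 with an estimated correlation) and against monocyte-like cells by -0.45 (camera adjusted p = 0.00551, adjusted p = 0.638 with an estimated correlation).

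The fall of proliferation genes in p21CE macrophage-like cells was weighed against 3 technical explanations. A difference in UMIs per cell points the other way, since both p21CE medians exceeded both p21WT medians by at least 3272 UMIs, which would raise their share of cycling cells. T or B cells caught with macrophages would leave the list near 0 once removed, but its median was -1.91 without them. An equal shift of every class of the p21CE libraries is hard to hold against the difference of -1.86 from cDC2-like cells. Ube2c, however, also went from 46.3 to 21.2 CPM in B cell-like and from 138 to 85.3 CPM in T and innate lymphoid-like cells. In neutrophil-like cells it went from 210 to 122 CPM. The other named proliferation genes were lower in these classes too, except Cenpe in B cell-like cells (12.5 and 14.4 CPM). A fall shared by several classes is thus not excluded. Fewer cycling macrophages in p21CE tumours may explain the fall in this class. The labels leave open whether the construct, the tumour or the pooled animals caused it.

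Setd5 (ENSMUSG00000034269) and the lincRNA Gm42031 differed between p21CE and p21WT in all 7 cell classes examined, and both were picked after the values were seen. Setd5, on chromosome 6 at 113077365 to 113153435, lies 32 bp from Gt(ROSA)26Sor, a locus into which reporter constructs are often placed. Its log2 shift was between 1.24 and 2.08, while Gm42031, on chromosome 8 at 85125872 to 85132289, went from 139 to 3.61 CPM in macrophage-like cells. Of 9163 genes with enough UMIs, 16 shifted by at least 0.8 log2 in every class.

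For Setd5 and Gm42031, free macrophage RNA was argued against, since B cell-like cells held 171% and 74.8% of their macrophage CPM, whereas C1qa, a macrophage gene, had 2.40% and 2.32%. In cDC2-like cells Setd5 was shifted by 2.14 in the 633 without a YFP UMI, against 1.91 in the 192 with one. The shift was thus not confined to cells with a YFP UMI. Recombined cells alone are not excluded, since a cell without a YFP UMI may still be recombined. The gene had also been picked for shifting in this class, where most cells had no YFP UMI. Setd5 was shifted by 1.39 (1.27 to 1.51) in T and innate lymphoid-like cells without a YFP UMI, but since it was picked for shifting in every class, an insertion or strain sequence carried by all cells cannot be told apart from other causes. The 19 other expressed genes within 1000000 bp had macrophage log2 shifts from -0.86 to 0.59, and 0 of them shifted in every class. The labels do not give the locus of the construct, so it was not tested further.

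A cluster of barcodes with genes of oligodendrocytes, the myelin-forming cells of the brain, was found in both steady-state libraries, which no label mentions. It held 142 and 178 barcodes with median UMIs of 1067 and 1076, and 140 barcodes were the same in both libraries. That is 98.6% (95.005 to 99.8) of the smaller set, against 0.088% in macrophage-like clusters, 11.8% among acinar-like cells, 29.5% in a cluster led by Cspg5 and 3 of 3 barcodes in one led by Gpr84. Barcodes swapped in from another library sequenced alongside could explain the oligodendrocyte-gene barcodes, and cells of the sorted pancreas are argued against. The 2 libraries shared 4.68 barcodes per 1000000 pairs over all kept cells, against 0.172 to 0.400 in the 35 other pairs of libraries.

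The chemotherapy library held a cluster of 152 cells with no clear immune markers, 2.07% (1.76 to 2.42) of its kept cells, against 5 of 10659 with vehicle. Its leading genes, Hmga2, Stmn2, Cdkn2a and Tm4sf1, are not immune genes, and the difference was not tested.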

How the results depend on the processing

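All tests of this part but those without T or B cell markers, those at 200 genes, those with an unnamed p21 cluster added and the list tests on other sets of cells were chosen before the result was seen. Of 1233 values of named genes in p21CE against p21WT, 1212 kept their direction and side of the threshold under the alternatives, as did 169 of 195 for lists. Of 476 gene values and 105 list values in tumour against steady state, 463 and 94 were kept. Over the KPC libraries alone the MHC class II median was -0.01 (0.30 over all) and those of interferon response (-0.73), MHC class I (-0.46) and phagocytic receptor genes (0.36) left the range of random lists, as did MHC class II over the p21WT libraries (0.42) and phagocytic receptors with the unnamed cluster added (0.38), and the cause was not tested. Of class shares, 102 of 119 (p21CE) and 37 of 51 (chemotherapy) were kept, and of 1 library against 1, 160 of 246 gene values and 63 of 90 list values. The macrophage count of 6851 genes was 4827 in DESeq2 and 5096 to 7131 with a library left out. At 1.5-fold edgeR recovered 38.8% of simulated genes in cDC1-like and 41.8% in monocyte-like cells, so small changes can be missed there, and whether depth is the limit was not tested.

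Other counts of genes depended on the setting, and the cause was not tested. Monocyte-like cells (806 genes) had 335 in DESeq2 and 502 to 1045 with a library left out. The cDC2-like count (1890) was 882 in DESeq2 and 1049 to 2367 with a library left out. The cDC1-like count (379) was 1051 with no low-count filter, 180 with stricter cell filters, 1074 with the replicate number as a block, and 28 (40 without the other p21WT library) to 962 with a library left out. With that block the counts were 7004, 784 and 2411 in macrophage-like, monocyte-like and cDC2-like cells. Libraries of the same number did not deviate together (correlations 0.02, -0.04, 0.04 and -0.04), so the block was not used. Of the 15 lists 0 passed with an estimated correlation (5 at unadjusted p under 0.05 in camera, 11 past the threshold in fry), and 10 to 14 with a library left out, and the cause was not tested.

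Class shares moved with cell filters, and the cause was not tested. In p21CE minus p21WT, B cell-like cells had -3.42 points with doublets kept, T and innate lymphoid-like -5.42, macrophage-like -10.7 and neutrophil-like 17.9 with stricter filters, and macrophage-like -11.7 at 200 genes. The stricter filters turned the difference for mast cell-like (-0.600) and unnamed cells (-0.131). After chemotherapy, B cell-like cells had -10.4 points with doublets kept and -7.12 with stricter filters, T and innate lymphoid-like -10.7 and -10.2, neutrophil-like 21.001 and 28.4, and macrophage-like -8.94 with stricter filters.

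Without thinning, the difference in cells with an Mki67 or Top2a UMI was -5.85 points (p21CE), 4.23 (YFP-positive), -6.52 (chemotherapy) and 27.8 (tumour), which carries depth differences. With at least 2 UMIs over the whole proliferation list almost every cell counted, about 99%, and the differences were -0.426, 0.462, 0.325 (turned) and 0.233 points. For Cdkn1a in macrophage-like cells after chemotherapy, log2 was -0.32 with TMM factors, -0.32 with doublets kept and -0.24 with stricter filters, where Ctss (-0.033) and Lyz2 (-0.10) turned and the proliferation list median was 0.16, and the cause was not tested. The steady-state, KPC and chemotherapy sets had no monocyte-like cluster, so adding such cells gives no separate value there.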

Other observations

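The tests on sex and on YFP in this part were chosen before their result was seen, and the narrower depth range was among tests chosen only after the result was seen.

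Other classes of the chemotherapy library shared part of the macrophage genes. In neutrophil-like cells the monocyte attractants Ccl7 (122 against 10.8 CPM, 11.2-fold), Ccl8 (73.5 against 6.93 CPM, 10.6-fold) and Ccl2 (145 against 18.6 CPM, 7.77-fold) and the interferon-induced Ifit1 (52.6 against 6.93 CPM, 7.59-fold) were higher than with vehicle, and the protease inhibitor gene BC100530 was highest (172 against 11.3 CPM, 15.3-fold). The chaperones Hspa1b (17.7 against 183 CPM) and Hspa1a (32.8 against 309.8 CPM) were lower. In T and innate lymphoid-like cells Xcl1, which attracts cDC1, had 105 against 11.1 CPM (9.42-fold, 6.97 to 12.9), and in B cell-like cells Ccl2 had 103 against 9.21 CPM. The median of macrophage markers was higher after chemotherapy by 1.11, 1.27 and 1.18 in neutrophil-like, B cell-like and T and innate lymphoid-like cells, so chemokine mRNA there may partly come from macrophages. Interferon response genes were higher in 23 of 32 in neutrophil-like cells (median 0.44) and lower in 23 of 31 in B cell-like cells (median -0.58).

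In cDC2-like cells of p21CE tumours, genes of monocyte origin fell, with 10 of 20 down and 4 up (camera adjusted p = 1.54e-05, adjusted p = 0.187 with an estimated correlation), and interferon response genes had 9 of 32 down and 2 up (camera adjusted p = 0.00179, adjusted p = 0.3 with an estimated correlation). MHC class II, which fell in macrophage-like cells, did not change as a list there, with 2 of 14 up and 1 down (camera adjusted p = 0.391, adjusted p = 0.702 with an estimated correlation). Hypoxia and glycolysis genes rose in cDC1-like cells too, with 6 of 25 up, 14 adjusted over the list alone (camera adjusted p = 4.27e-10, adjusted p = 0.375 with an estimated correlation).

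Sex-linked genes differed between libraries. Xist, expressed in females, had 747 CPM with vehicle and 584 CPM after chemotherapy, and the Y-linked Ddx3y 0 and 38.6 CPM, so the chemotherapy library held cells of both sexes. It was asked whether sex could explain the lower share of cycling macrophages after chemotherapy. Among cells with Xist and no Y-linked UMI, the share was 24.4% with vehicle and 14.8% after chemotherapy, a difference of -9.60 points (-11.7 to -7.49), which argued against sex. Within the chemotherapy library, cells with Y-linked UMIs differed from cells with Xist by 1.84 points (-1.18 to 5.01).

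It was also asked whether only p21CE macrophages with the reporter cycled less. In the first p21CE library the share of cells with an Mki67 or Top2a UMI was 7.82% with and 18.1% without a YFP UMI (-10.2 points, -15.2 to -5.81), and in the second 9.61% and 16.03% (-6.43 points, -11.9 to -1.69). Cells without a YFP UMI were shallower, with median UMIs of 10001 and 9498 against 22833 and 24623. Between 5000 and 15000 UMIs the differences were -7.04 points (-13.6 to -1.14) and -1.52 points (-9.41 to 5.60). The first library is consistent with an effect within cells that carry the construct, and the second leaves it open.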
